A study of Mus musculus with 2 samples.

How the data were processed

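H3K9me3 ChIP-seq libraries were made from midbrain of embryonic day 13.5 mice in 2 biological replicates, each from pooled male and female embryos. The labels give biological replicate numbers for separate tissue samples and a size range of 300 to 500 for both libraries. Per the labels, replicate 1 combines 2 technical replicates and was sequenced on 2 models of Illumina HiSeq instrument, and replicate 2 has 1 technical replicate. Both replicates form 1 group, because no label separates them by anything else, and no comparison between groups was made.

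All values come from 4 deposited peak lists on mm10, with peaks as rows and no header line. Per the deposited readme texts, each replicate's list was called from its own filtered alignments against 1 control file, and the control files of the replicates differ. The pooled list was called on both replicates' alignments together, and the replicated list was derived from the pooled list and both replicate lists. The peak caller, the aligner and their thresholds are not given in the sources used here. The fold enrichment of each peak, a ratio of ChIP over control signal, was computed by the authors, and is read here from the column position of the narrowPeak format. The deposited −log10 p and −log10 q of each peak were also computed by the authors, and the lowest deposited −log10 p was 2.04 in replicate 1 and 2.04 in replicate 2. Read depth is unknown, so weak peaks in a deeper library cannot be set apart from a stronger signal, and fold values were not compared between lists as a change. Calling against different controls can also move peak numbers between the replicates.

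The reference was GRCm38.p6, the mm10 assembly, whose chromosome lengths match the build, with its soft-masked FASTA and the GENCODE vM21 annotation. Peaks on autosomes, X and Y were tested, and peaks on scaffolds (398, 382, 381 and 273 in the replicate 1, replicate 2, pooled and replicated lists) were left out of the tests. Every replicated peak is also a peak of the pooled list. Each base was put in a single annotation class, in the order promoter (1 kb either side of a gene start), exon, intron and intergenic. A gene counted as overlapped when a peak shared at least 1 bp with its annotated span. Pattern lists took protein-coding genes by symbol, and named lists took any gene type, with every symbol found.

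The main test shifted the peaks of a list around each chromosome by a random offset after removing assembly gaps, which keeps gene lengths, gene clusters and peak clusters. It was repeated 100000 times for main results and 10000 times for alternatives, and gave a two-sided permutation p, with Benjamini-Hochberg adjustment within each family (13 gene lists, 4 annotation classes, 3 counts of Zfp gene parts, 2 content shares and 2 replicate overlaps) at a threshold of 0.05. The smallest p this can give is 2e-05 for main results and 0.0002 for alternatives. The p-values describe where peaks lie relative to the annotation, and the spread between the replicates is given beside them as mean ± SD. A shifted peak can land in sequence where reads cannot be placed, which can change the expected values by an amount that was not measured. At shifted positions 14.5% had a median above 1 genome copy for 5 sampled 31-mers, against 3.62% of replicated peaks. Tested on simulated peak sets, the gene list test gave p under 0.05 in 2.38% of unplanted tests over 2226 listed genes, and in 100% of 100 sets with peaks planted in 100 Zfp genes. The unplanted sets were the replicated peaks moved by the same kind of shift. Their rate therefore checks the computation and cannot show error from sequence where reads cannot be placed. Replicate overlaps counted with bedtools were 17354 and 13872, against 17355 and 13872 in gap-free coordinates.

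Named genes followed a rule set before the data were examined. It took up to 4 members of each list with the highest-fold overlapping replicated peak, and the genes at or nearest to the 10 replicated peaks of highest fold on assembled chromosomes. It also took the 10 genes of at least 5 kb with the largest covered share that were covered over at least 10% in both replicates, and the 10 widest replicated regions. For midbrain and housekeeping genes it added up to 4 members without any peak. Alternatives set before the data were examined were peaks with a −log10 q of at least 2, other overlap rules, equal list lengths, and a recomputed replicated set. They also included gene starts, spans with 5 kb added, random genes matched on length in 20 bins, at least 10% of the span covered, a promoter of 2 kb, gene ends of 2 kb, each replicate's own list, the pooled list, and autosomes only. The restriction to peaks whose 5 sampled 31-mers each occur once in the genome was added after the files had been read. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0, bedtools 2.31.1 and matplotlib 3.10.9.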

Results

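H3K9me3, trimethylation of lysine 9 on histone H3, marks heterochromatin and is commonly found over silenced genes and repeats. Its positions were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in midbrain dissected from embryonic day 13.5 mice of strain B6NCrl, with male and female embryos pooled. The series held 1 group of 2 biological replicates, so there was no second tissue, stage or genotype to compare, and the comparisons were between the replicates and between peaks and the mm10 genome annotation. The deposited values were 4 peak lists. Replicate 1 had 67910 peaks of its own and replicate 2 had 71372, while 84220 peaks were called on both replicates pooled and 28993 of these formed the authors' replicated list. The number of reads behind each list is unknown, so no counting interval could be given for a peak. Peak fold enrichments are the authors' own values and are used only to describe and rank peaks within a list.

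The first comparison asked how far the replicates marked the same places. Of the 67512 replicate 1 peaks on the assembled chromosomes, 17355 (25.7%) had at least 50% of their length inside a replicate 2 peak, against a mean of 633 (95% range 496 to 848) when one list was shifted along the chromosomes. In the other direction 13872 of 70990 replicate 2 peaks (19.5%) were covered by replicate 1, against 493 (386 to 656). Both excesses had a two-sided permutation p of 2e-05, the smallest that 100000 shifts can give, and an adjusted p of 2e-05 over the pair of tests. Sharing was most frequent among the peaks of highest fold. In the decile of highest fold enrichment 51.7% of replicate 1 peaks and 42.0% of replicate 2 peaks were shared, whereas in the lowest decile the shares were 18.9% and 13.6%. A −log10 q of 2, which also depends on the unknown depth and on the control, was reached by 14.5% of replicate 1 peaks and 45.7% of replicate 2 peaks. With both lists cut at a −log10 q of 2, 40.8% of replicate 1 peaks and 9.76% of replicate 2 peaks were shared. That cut kept unequal parts of the lists, so it was not equally strict. With an overlap of 1 bp and no such cut the shared shares were 33.8% and 30.8%. With 90% of the peak they were 12.1% and 5.59%.

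**Figure D1:**
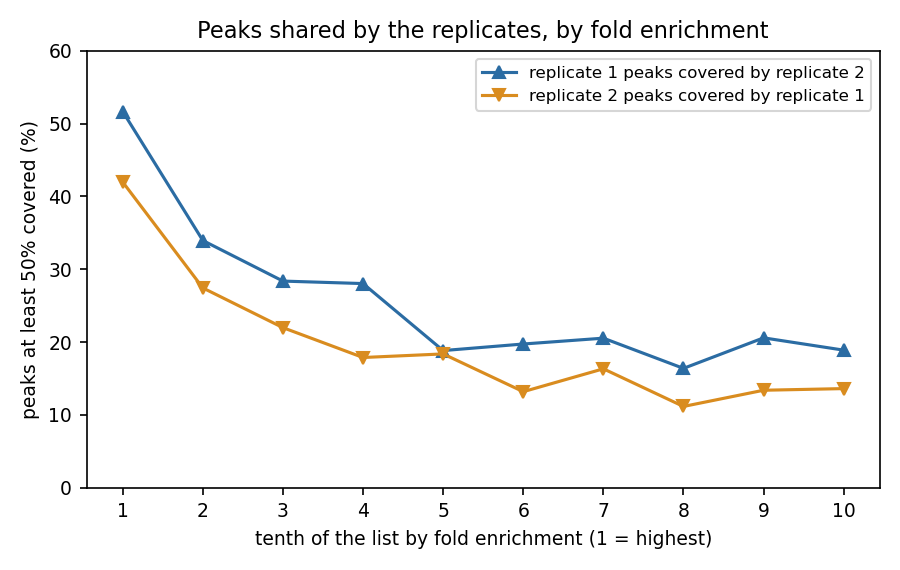
Share of peaks in each replicate with at least 50% of their length covered by the other replicate's peaks (vertical axis, percent), for 10 equal parts of the replicate's own list ordered by fold enrichment (horizontal axis, 1 is highest); triangles are replicate 1 and inverted triangles replicate 2. The share is 51.7% and 42.0% in the strongest part and 18.9% and 13.6% in the weakest.

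Replicated peaks were wider and of higher fold than the rest of the pooled list. It held 34.4% of pooled peaks (95% Wilson interval 34.1 to 34.7, counting error only), with a median width of 391 bp and a median fold of 3.62. The 55227 other pooled peaks had a median width of 208 bp and a median fold of 2.84. Peaks of both replicates touched 71.9% of the replicated peaks and 1.32% of the others. Replicate 1 peaks touched 81.7% of the replicated peaks and replicate 2 peaks 89.4%, so some lacked a peak in a replicate's own list. These contrasts are not independent of how the replicated list was derived from the replicate lists. Replicated peaks on the assembled chromosomes covered 13.8 Mb, or 0.523% of non-gap sequence. Replicate 1 alone covered 0.636% and replicate 2 alone 0.796%. When peaks were instead required to be at least 50% covered by both replicates' lists, 16.6% of pooled peaks qualified.

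Some of the 10 replicated regions of highest fold on the assembled chromosomes lay over a transcription factor gene, zinc-finger genes or the protocadherin cluster. The highest, at chromosome 6, 30955912 to 30959465 (fold 13.6), overlapped Klf14, a Krüppel-like transcription factor gene, and reached fold 10.4 in replicate 1 and 14.2 in replicate 2. Ranks 3, 7 and 10 overlapped Zfp180, Zfp873 and Zfp810 (fold 9.58, 8.79 and 8.60), genes of C2H2 zinc-finger proteins. Rank 8, at chromosome 17, 21920589 to 21921353, overlapped a processed pseudogene and lay 5606 bp from Zfp942, another zinc-finger protein gene. Rank 9, at chromosome 18, 37746682 to 37750204, lay at the start of Pcdhga10, within the spans of the upstream gamma protocadherins. The other 4, at ranks 2, 4, 5 and 6, overlapped no annotated gene. Their nearest protein-coding genes were Zfy1 on Y (465678 bp away), 2010315B03Rik on chromosome 9 (21789 bp), Gm1993 on X (182177 bp) and Btbd35f25 on X (19587 bp). The Y region was repeated sequence, with a median of 30 genome copies of its sampled 31-mers, and the Btbd35f25 and Zfp942 regions had medians of 3 and 2.

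The annotation comparison asked in which parts of genes the mark lay. Replicated peaks held more promoter and exon sequence and less intron sequence than shifted peaks. Promoters, taken as 1 kb either side of a gene start, made up 6.99% of covered bases against 4.22% for shifted peaks (95% range 3.66 to 4.87). Exons made up 6.43% against 4.29% (3.70 to 4.92), introns 31% against 41.7% (38.3 to 45.2) and intergenic sequence 55.6% against 49.8% (46.0 to 53.4). The two-sided permutation p was 2e-05 for promoter, exon and intron (adjusted p = 2.7e-05 over 4 classes) and 0.00158 for intergenic sequence (adjusted p = 0.00158). The replicates' own lists gave 5.73% ± 0.40 promoter, 5.28% ± 0.03 exon, 32.3% ± 0.24 intron and 56.7% ± 0.13 intergenic sequence (mean ± SD, n = 2). Peaks were richer in G and C than shifted peaks, at 45.7% against 42.1% (permutation p = 2e-05, adjusted p = 4e-05), with 45.5% ± 0.56 in the replicates (SD, n = 2). The soft-masked repeat share was slightly lower, at 32.2% against 33.9% (permutation p = 0.0107, adjusted p = 0.0107), with 32.6% ± 0.41 in the replicates (SD, n = 2). Multi-copy sequence made up 14.5% of shifted positions and 3.62% of replicated peaks, and no alternative removed this difference. The lower repeat share therefore cannot be separated from where reads can be placed. The same difference can change the expected G and C share and annotation shares, by an amount that was not measured.

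The main question was which genes carried the mark. Across all 21938 protein-coding genes, 3427 (15.6%) overlapped a replicated peak. Of 13 gene lists set before the data were examined, 5 were overlapped more often than by shifted peaks. These were zinc-finger genes, clustered protocadherins, vomeronasal receptors, germline genes and imprinted genes. None of the other 8 passed the threshold in either direction. All adjusted p-values of the lists come from a two-sided permutation test with Benjamini-Hochberg adjustment over the 13 lists.

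Zinc-finger genes with a Zfp number, many of which encode KRAB-domain repressors, were overlapped in 159 of 391 cases, against 65.7 for shifted peaks (95% range 46 to 91, permutation adjusted p = 0.00013). In the replicates' own lists 51.5% ± 1.6 of them had a peak (SD, n = 2), or 197 and 206 genes, against 132.4 and 130.1 for shifted peaks of those lists, so the ratio fell from 2.42 to 1.49 and 1.58. The peaks at Zfp180 (chromosome 7, 24081924 to 24107713) and Zfp873 (chromosome 10, 82048123 to 82064745) lay over the last exon, and replicated peaks covered 51.3% and 79.1% of these genes. In the replicates the covered share was 44.2% ± 10.8 for Zfp180 and 67.9% ± 10.8 for Zfp873 (SD, n = 2). Zfp810 was covered over 31.2% (22.9% in replicate 1 and 29.8% in replicate 2) and Zfp286 over 21.8% (13.3% and 24.5%). The peak of highest fold lay over the last exon in 74 of the 159 overlapped genes, in an intron in 56, in another exon in 25 and at the gene start in 4. The last exon of the longest transcript was overlapped in 98 genes against 15 for shifted peaks (5 to 30, permutation p = 2e-05, adjusted p = 3e-05), while 1 kb either side of the gene start was overlapped in 14 against 12.7 (4 to 26, permutation p = 0.777). The difference of 84 genes exceeded the 2.24 of shifted peaks (permutation p = 2e-05, adjusted p = 3e-05) and was 100 in replicate 1 and 102 in replicate 2, against 5.08 and 4.96 for shifted peaks of those lists. At gene starts alone the whole list was therefore not enriched (ratio 1.10, permutation adjusted p = 1.00).

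Clustered protocadherins, cell-surface adhesion proteins whose variants are chosen stochastically in neurons, were overlapped in 52 of 56 genes against 17.5 (0 to 35, permutation adjusted p = 0.0039). Replicate 1 marked 52 against 30.04 and replicate 2 marked 53 against 28.9, ratios of 1.73 and 1.83. Here the gene starts themselves were marked, in 51 genes against 1.26 for shifted peaks (permutation adjusted p = 0.00087). Pcdhga1, Pcdhga2 and Pcdhga3 were covered over 47.5%, 47.8% and 47.0% of their spans and Pcdhga10 over 23.9%, against 41.7% ± 5.7, 41.9% ± 5.5, 41.7% ± 5.3 and 21.0% ± 2.6 in the replicates (SD, n = 2). These spans share their 3′ exons and overlap, so the genes are not independent. The 4 members without a replicated peak, named after their values were seen, were Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, all C-type variants. Pcdhac1, also a C-type variant, counted as overlapped through its span. It had no peak at its start in the replicated list or in either replicate's list. The 1 Mb window that holds most of the cluster, chromosome 18 from 37000001 to 38000000, was the most densely marked of 2716 windows, with 306 replicated peaks over 23.3% of its length (17.7% in replicate 1 and 22.6% in replicate 2).

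**Figure D2:**
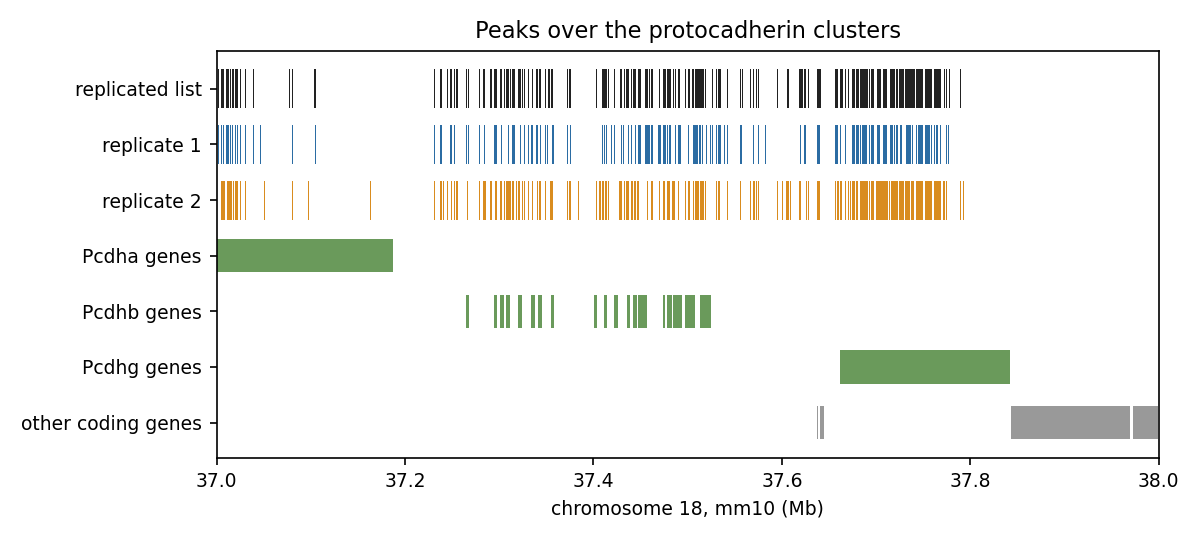
Map of chromosome 18 from 37000001 to 38000000 in mm10 (horizontal axis, Mb), with peaks of the replicated list and of each replicate above the annotated spans of the alpha (Pcdha), beta (Pcdhb) and gamma (Pcdhg) protocadherins and other protein-coding genes; overlapping spans are drawn on top of each other. Peaks cover 23.3% of the window in the replicated list, lie along the beta and gamma clusters in both replicates, and are nearly missing over the other protein-coding genes on the right.

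Vomeronasal receptors, the pheromone receptors of the vomeronasal organ, were overlapped in 105 of 326 genes against 41.6 (22 to 70, permutation adjusted p = 0.00061), with 40.3% ± 1.1 in the replicates (SD, n = 2). The replicates' 134 and 129 genes compare with 83.1 and 81.7 for shifted peaks of their own lists, so the ratio fell from 2.52 to 1.61 and 1.58. Of these 105 genes, 54 lay on chromosome 7 and 38 on chromosome 17. Covered shares were 9.54% for Vmn2r10 (2.38% in replicate 1 and 10.1% in replicate 2), 8.61% for Vmn2r105 (9.62% and 13.6%), 6.68% for Vmn2r58 (6.95% and 8.34%) and 27.2% for Vmn1r179 (20.7% and 29.8%). Counting gene starts only, 31 were overlapped against 13.6, which did not pass the threshold (permutation adjusted p = 0.196). Olfactory receptors were overlapped in 111 of 1092 genes against 66.1 (33 to 121, permutation adjusted p = 0.164). Their strongest members were Olfr354, Olfr1477, Olfr362 and Olfr643, at fold 5.54 for the first and 5.16 for the others. In the replicates' own lists 204 and 187 olfactory receptors had a peak against 142.1 and 141.5 (permutation adjusted p = 0.0769 and 0.209). Against random protein-coding genes of matched length the olfactory count passed (55.7 expected, 43 to 69, permutation adjusted p = 0.00052). Those genes were drawn singly, without the gene clusters that the shift keeps, so this p does not allow for clustering. Defensins, antimicrobial peptides, were overlapped in 5 of 64 genes against 1.66 (0 to 6, permutation adjusted p = 0.175), with Defb4, Defb33, Defb39 and Defb5 at folds of 4.40, 4.36, 3.25 and 3.06. No replicate 1 peak overlapped this peak of Defb33. In replicate 1's own list 13 defensins had a peak against 4.08 (permutation adjusted p = 0.0204), and in replicate 2's list 11 against 4.05 (permutation adjusted p = 0.0875).

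Imprinted genes, listed here for parent-of-origin expression or for hosting an imprinting control region, were overlapped in 33 of 40 cases against 10.1 (5 to 15, permutation adjusted p = 0.00013). In the lists of replicates 1 and 2 they were overlapped in 35 and 37 cases against 18.4 and 17.9. Gene starts were marked in 16 genes against 1.30 (permutation adjusted p = 0.00087), 17 in replicate 1 and 19 in replicate 2. Some members share a peak, such as that at the starts of Peg10 and Sgce (chromosome 6, 4747727 to 4748495), so the genes are not independent. The strongest peak was at the start of Zrsr1 (chromosome 11, 22971731 to 22972724, fold 6.31), which lies within Commd1. Next was the peak at the start of the annotated 62.4 kb span of Gnas (chromosome 2, 174284100 to 174285508, fold 5.73), the gene of the stimulatory G protein alpha subunit. Other Gnas transcript starts within that span were not examined separately. The peak therefore cannot be placed at the start of the subunit's own transcript. The same peak overlaps the span of Nespas, the antisense RNA gene of Gnas. Covered shares were 21.1% for Zrsr1 (6.03% in replicate 1 and 32.5% in replicate 2), 5.04% for Commd1 (1.58% and 6.37%), 14.2% for Gnas (10.1% and 12.9%) and 26.2% for Nespas (14.9% and 25.3%). Germline genes, used in meiosis and germ cells, were overlapped in 14 of 30 cases against 6.21 (2 to 11, permutation adjusted p = 0.0045). The peak at Mael, a piRNA pathway gene, lay at its start (chromosome 1, 166238418 to 166238784, fold 4.59), and those at Tdrd9, Tdrd1 and Dmrt1 were intronic (fold 4.59, 4.40 and 4.04). Gene starts were marked in 8 germline genes against 0.665 (permutation adjusted p = 0.00087). The replicates' own lists had 19 and 18 germline genes with a peak against 13.8 and 13.2, and neither count passed the threshold (permutation adjusted p = 0.0933 and 0.147).

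The midbrain and neural list and the housekeeping list had few genes with a replicated peak, but both counts lay within the range of shifted peaks. Midbrain and neural genes were overlapped in 2 of 30 cases against 5.77 (2 to 10, permutation adjusted p = 0.150). The exceptions were Pax3 and Pax5, paired-box transcription factor genes, with peaks of fold 3.95 and 3.82 covering 0.778% and 0.135% of their spans. In replicates 1 and 2 the shares were 0.462% and 0.750% for Pax3 and 0.171% and 0.312% for Pax5. En1, En2, Otx2 and Lmx1b, transcription factor genes of midbrain patterning, had no peak in the replicated list or in either replicate. In the replicates' own lists 10 and 9 midbrain and neural genes were overlapped against 11.7 and 11.4, ratios of 0.858 and 0.788 (permutation adjusted p = 0.769 and 0.525). In the pooled list 5 were overlapped against 12, which passed (permutation adjusted p = 0.0052). No housekeeping gene of 30 had a replicated peak against 2.94 (0 to 6, permutation adjusted p = 0.164), and Actb, Gapdh, Ppia and Rpl13a had none in either replicate. In replicate 2's list 2 housekeeping genes had a peak against 6.71 (permutation adjusted p = 0.0875). The single housekeeping gene in the replicate 1 list and the single one in the pooled list were below the expected 6.66 and 7.20 (permutation adjusted p = 0.0187 and 0.0109). No Hox gene of 39 had a replicated peak against 1.89 (permutation adjusted p = 0.575), whereas the replicates' own lists had 6 and 7 against 4.76 and 4.64, ratios of 1.26 and 1.51 (permutation adjusted p = 0.801 and 0.529). Markers of blood, vessels, mesenchyme and microglia that a dissection could include were overlapped in 3 of 30 cases against 4.49 (permutation adjusted p = 0.665), at Pdgfrb, Tek and Pecam1 with fold 5.16, 3.32 and 2.87. No replicate 2 peak overlapped the peak at Pecam1. The replicates' own lists had 10 and 8 of these markers against 9.68 and 9.55. Genes of other organs had 1 of 30, the pancreatic transcription factor gene Pdx1 (fold 4.40), against 3.03 (permutation adjusted p = 0.487). The replicates' own lists had 6 and 6 other-organ genes against 6.52 and 6.32. Among 68 genes of testis and reproductive families, 67 of them on X and Mageb3 on chromosome 2, Rhox6 alone had a replicated peak (fold 3.44), against 2.23 (permutation adjusted p = 0.841). No replicate 1 peak overlapped that peak. The replicates' own lists had 4 and 12 of these 68 genes against 6.83 and 11.2.

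**Figure D3:**
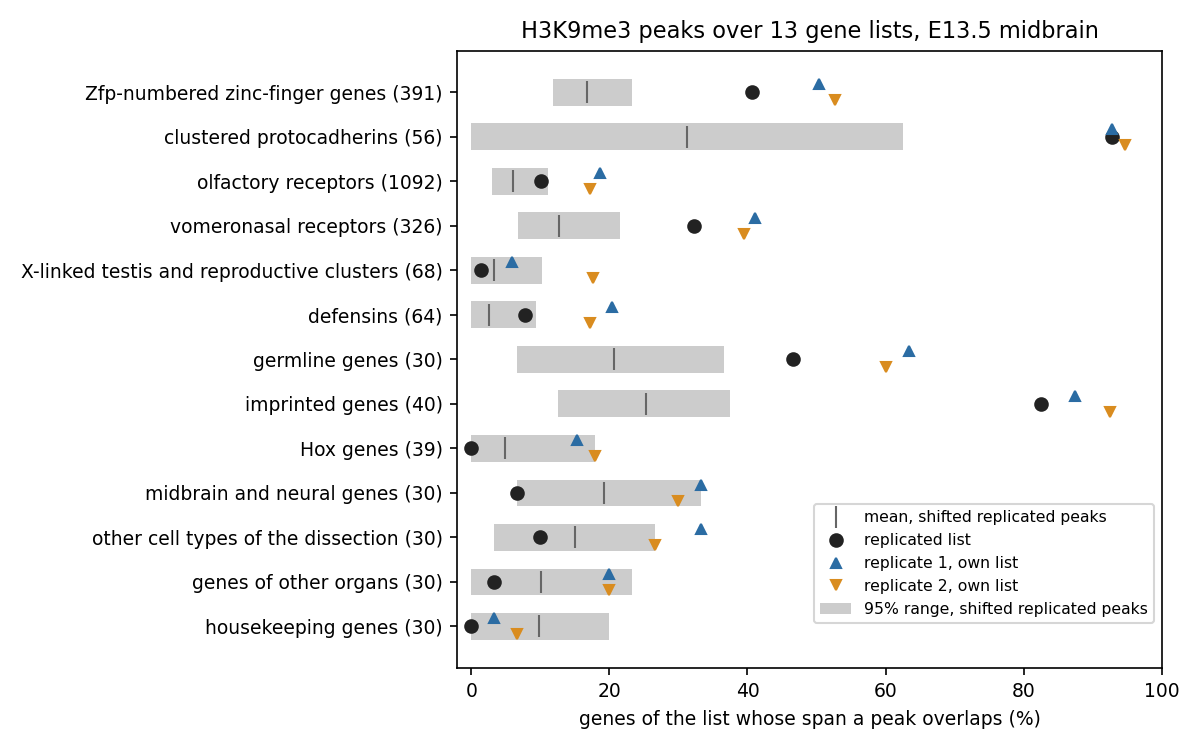
Share of genes in each of 13 lists (size in parentheses) whose annotated span a peak overlaps (horizontal axis, percent). Black points are the replicated list, triangles replicate 1, inverted triangles replicate 2, and grey bars and ticks the 95% range and mean of shifted replicated peaks, which apply to the black points only. Zinc-finger genes (40.7%), clustered protocadherins (92.9%), vomeronasal receptors (32.2%), germline genes (46.7%) and imprinted genes (82.5%) lie above the bars.

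Some genes were covered over most of their length in the replicated list. Among protein-coding genes of at least 5 kb that were covered over at least 10% in both replicates, the highest was Ugt1a1 (chromosome 1, 88211959 to 88218997), the bilirubin-conjugating enzyme, at 92.8% in the replicated list and 91.6% ± 0.24 in the replicates (SD, n = 2). Its neighbour Mroh2a (88226986 to 88262289) followed at 88.8%, with 85.8% ± 6.0 (SD, n = 2), and held 3 of the 10 widest replicated regions, of 16416, 9815 and 6669 bp. Significance at Ugt1a1 and Mroh2a was high for the fold. Their peaks of highest fold had a −log10 q of 40.5 and 28.5 at folds of 4.75 and 4.35. That of Zfp873 had 26.0 at fold 8.79, and that of Defb33 had 6.10 at fold 4.36. The reason was not tested, so the wide coverage there may not mean a stronger mark. Smok2b on chromosome 17 was covered over 85.3% (56.5% in replicate 1 and 79.7% in replicate 2) and Asmt on X, the gene of the last enzyme in melatonin synthesis, over 84.6% (76.6% and 82.0%). Zfp873, Zfp110 and Zfp2, all zinc-finger genes, were covered over 79.1%, 78.0% and 74.6%. In replicates 1 and 2 Zfp110 stood at 54.7% and 70.0% and Zfp2 at 51.8% and 69.1%. Defb33, Igfl3 and Ceacam11 were covered over 77.8%, 73.8% and 73.2%. Their shares in replicates 1 and 2 were lower, at 18.3% and 71.7% for Defb33, 51.9% and 34.5% for Igfl3 and 50.2% and 66.5% for Ceacam11. Of the other 7 wide regions, 1 overlapped protein-coding genes, Sfi1 and Drg1 on chromosome 11 (3190964 to 3197214). Of the 6 others, 3 lay on chromosome 3 from 3021293 to 3033640 and on chromosome 4 from 3061675 to 3070004 and from 3049960 to 3056630. A further 3 lay on chromosome 17 (13211408 to 13219453, 1734 bp from Smok2a), chromosome 13 (12925581 to 12932528, 63596 bp from Prl2c2) and chromosome 4 (122032338 to 122038653, 410234 bp from Gm12887).

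Coverage was uneven between chromosomes. Chromosome 7, which carried 4611 replicated peaks, was covered over 1.67% of its non-gap length, 3.19 times the genome share, followed by chromosome 17 at 1.91 times and chromosome 4 at 1.63 times. In the replicates' own lists chromosome 7 stood at 2.50 ± 0.10 times the genome share (SD, n = 2), chromosome 17 at 1.71 ± 0.02 and chromosome 4 at 1.39 ± 0.02. Chromosome X was covered at 0.275 times the genome share in the replicated list and at 0.538 ± 0.224 times in the replicates' own lists (SD, n = 2; 0.379 in replicate 1 and 0.696 in replicate 2). On X the replicates differed by more than on any other assembled chromosome, with 1735 peaks in replicate 1 and 3576 in replicate 2, a ratio of 2.06, while the ratio on the 19 autosomes ranged from 0.922 to 1.09. Peaks on Y numbered 28 and 20. No test of chromosomes was planned, and these values are given as description.

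**Figure D4:**
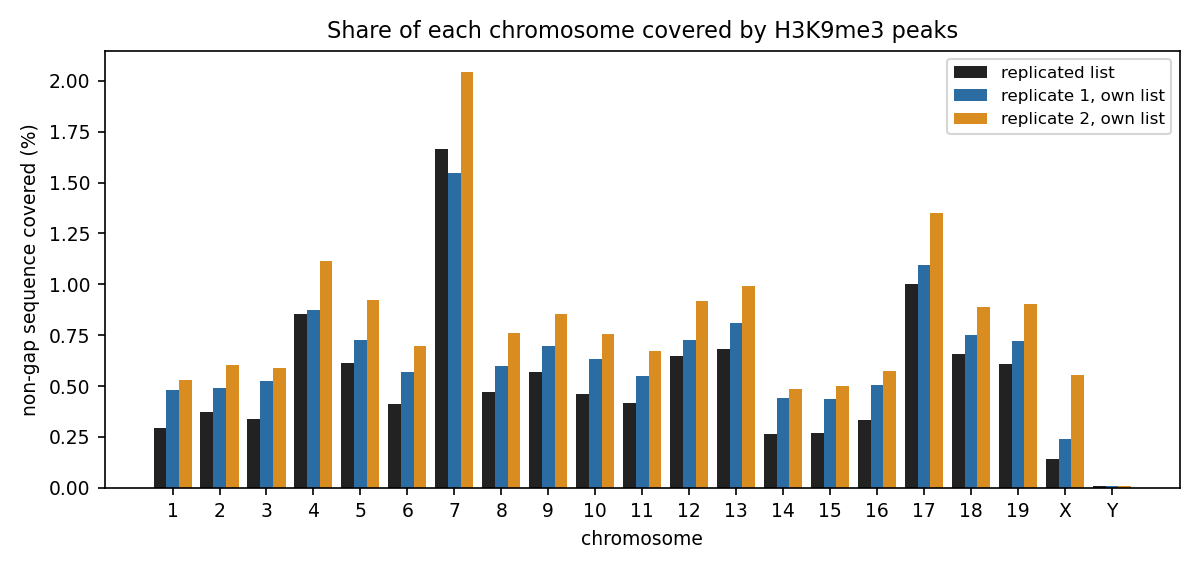
Share of each chromosome's non-gap sequence covered by peaks (vertical axis, percent) in the replicated list and in each replicate's own list; there are no error bars because each bar is a single list. Chromosome 7 is highest in every list (1.67% in the replicated list), and on X the covered share is 0.241% in replicate 1 and 0.555% in replicate 2.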

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

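The deposited lists hold signal outside the assembled chromosomes, on which no comparison was made. On 24 unlocalized and unplaced scaffolds there were 273 replicated peaks, 0.942% of the list, with a median fold of 3.68 and a median width of 537 bp, against a median fold of 3.62 on the assembled chromosomes. A single scaffold held 70 of them. With 1 group of 2 samples there was no test for a sample apart from the others and no contrast between groups.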

How the results depend on the processing

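The restriction to single-copy peaks and the X share of peaks at a −log10 q of 2 were chosen after seeing the data. The replicate overlap, the annotation classes and the repeat and GC shares kept their direction and their side of the threshold under every alternative run. So did the Zfp 3′ difference. No alternative for the overlap, the annotation classes or the repeat and GC shares left out multi-copy positions. The Zfp difference ranged from 60 to 109 genes. Imprinted genes and protocadherins passed under all 10 alternatives, at ratios of 1.90 to 14.0 and 1.73 to 65.2. Without replicate 1 or replicate 2 (the other replicate's own list), the ratio fell to 1.49 to 1.58 for Zfp genes and 1.58 to 1.61 for vomeronasal receptors, which passed. It was 1.36 to 1.38 for germline genes, which no longer passed, 2.72 to 3.18 for defensins, which passed in replicate 1's list, and 0.150 to 0.298 for housekeeping genes, which passed there too. It crossed 1, without passing, for X-linked testis genes (0.586 to 1.07), Hox genes (1.26 to 1.51) and other cell types of the dissection (0.838 to 1.03). In the pooled list defensins (3.0), midbrain and neural genes (0.418) and housekeeping genes (0.139) passed. At gene starts Zfp genes (1.10) and vomeronasal receptors (2.28) no longer passed, and X-linked testis genes stood above 1 (4.23), as they did with 5 kb added (1.46), without passing. Olfactory receptors passed against length-matched genes (1.99), which were drawn singly and do not keep gene clusters. With 10% of the span covered no germline gene counted (0 against 0.310). The replicated share of pooled peaks was 54.9% at a −log10 q of 2 and 16.6% when recomputed. Chromosome 7 stood at 2.43 to 2.57 times the genome share in the replicates and 2.66 in the pooled list, X at 0.379 to 0.696 in the replicates, and the X share of replicate 2 over replicate 1 was 2.59 at a −log10 q of 2. The cause of these changes was not tested. No autosomes-only value was computed for the X-linked testis list. Unknown depth limits all statements about genes without a peak.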

Other observations

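The tests with single-copy peaks and all tests of the X peak number were chosen after the results they examine had been seen. Besides protocadherins, vomeronasal and olfactory receptors and Zfp genes, some of the most densely marked windows held tandem gene families outside the fixed lists. The families were chosen after these windows had been seen, so only counts are given. The 27 most covered of 2716 windows of 1 Mb held 23.6% of all covered sequence. Placental cathepsins on chromosome 13 and Sult2a sulfotransferases on chromosome 7 had a replicated peak in 8 of 8 genes each, also in both replicates. Skint genes on chromosome 4, of the immunoglobulin superfamily, had one in 9 of 11, with 95.5% ± 6.4 in the replicates (SD, n = 2). Cyp3a genes, of drug and steroid metabolism, had one in 6 of 9, Mrgpra sensory receptors in 4 of 7 and Nlrp genes in 10 of 17. Pregnancy-specific glycoproteins (6 of 13), Ceacam genes (7 of 15), secretoglobins (11 of 29) and the Prame family (6 of 16) were marked in part.

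Immunoglobulin segments differed between chains. V segments of the heavy chain on chromosome 12 had a replicated peak in 42 of 113 genes, with 40 in replicate 1 and 52 in replicate 2. V segments of the kappa chain on chromosome 6 had none in 100, with 1 and 2 in the replicates. The window of chromosome 12 from 114000001 to 115000000 was the second most covered, at 17.7%. The difference between the chains was not tested.

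The order by significance differed from the order by fold. The most significant peak, on chromosome 11 from 3190964 to 3197214 over Sfi1 and Drg1, had a −log10 p of 150.8 at fold 3.70, whereas the peak at Klf14 had 59.3 at fold 13.6. Of the 10 most significant, 5 lay in this part of chromosome 11, and another pair on chromosome 17 overlapped a ribosomal RNA annotation (39842976 to 39848879) at folds of 2.98 and 2.99. The peak on Y (259034 to 259449) was among the first 10 in both orders, with a −log10 p of 118.6 at fold 12.6. Why the peaks on chromosomes 11 and 17 reached such significance at lower folds was not tested. Their significance may not mean a stronger mark there.

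The marking of clustered gene families was set against technical explanations. Paralogs share sequence, so misplaced reads could add peaks. With only replicated peaks whose sampled 31-mers each occur once in the genome, the count over the shifted expectation was 2.55 for Zfp genes (136 genes, permutation p = 0.0002), 3.29 for protocadherins (49 genes, p = 0.001 by permutation) and 2.59 for vomeronasal receptors (85 genes, permutation p = 0.0004), which argues against shared reads as the whole source. Against random genes of matched length, which need no shifted positions, the Zfp ratio was 3.17 (permutation p = 0.0002), so shifted peaks landing in sequence without callable peaks do not account for it. The random genes were drawn singly, so this p does not allow for gene clusters. No biological explanation was tested, since the design holds a single group.

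The doubled number of X peaks in replicate 2 was weighed in the same way. Among peaks with a −log10 q of at least 2, the X share in replicate 2 was 2.59 times that in replicate 1. This cannot decide whether weak peaks near the threshold made the difference, because the cut was not equally strict. It kept 14.5% of all replicate 1 peaks and 45.7% of all replicate 2 peaks. The X share fell under it in both lists, from 2.57% to 1.48% in replicate 1 and from 5.04% to 3.82% in replicate 2. A ratio above the highest autosome's 1.09 in 17 of 18 windows of 10 Mb (94.4%) argued against a difference confined to part of X. The exception was the last, incomplete window, from 170000001 to 171031299. It went the other way, with 24 peaks in replicate 1 and 17 in replicate 2, a ratio of 0.708. A rise of ChIP over control spread along X stays open as a candidate explanation, since peaks found in replicate 2 alone had a variance-to-mean ratio of 17.8 over 1 Mb windows of X, below the 55.9 of the highest autosome. This test was lenient, because any clustering up to that autosome's would have passed. The different control files, the technical replicates and different shares of male and female embryos in the pools also stay open, and none of these was tested.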
